A study of Arabis alpina with 12 samples.

How the data were processed

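Poly(A) RNA was sequenced from 12 samples of Arabis alpina, a perennial relative of Arabidopsis, in the accession Pajares. Per the labels' protocols, plants grew for 8 weeks in long days and were then vernalized, that is kept in the cold, for 8 weeks in short days. Main shoot apices and V3 buds were taken from wild type and from Aatoe2_IL, a line affected in AaTOE2, an APETALA2-like transcription factor, which gave 4 groups of 3 libraries. The lesion in Aatoe2_IL was not given in the sources used here. No other line affected in AaTOE2 was sampled, so that an effect of AaTOE2 cannot be told apart from other differences between Aatoe2_IL and wild type. Libraries were made with a strand-specific kit and read as single reads of 100 bp on a HiSeq2500, per the labels' protocols. The labels number the replicates but do not say that they came from separate plants, so that p-values measure only the spread between these samples, which may in part be technical.

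The deposited count table held whole-number read counts per gene, not normalized, and its last 5 entries were counters of reads outside genes, as the file itself shows. STAR, HTSeq 0.5.4p1, DESeq and DESeq2 were named in the submitters' processing notes without their roles. The genome build, the annotation and the strand setting of the counting were not given in the sources used here, so that overlapping and antisense genes are uncertain and no coordinates are printed. The authors' 4 deposited tables listed genes with a fold above 2 and an adjusted p-value under 0.05 between the genotypes, per the file headers. Their signal columns were group means of normalized counts, which matched the deposited counts divided by median-of-ratios size factors of the 6 libraries of that tissue within 0.5% for 732 of 732 entries. The deposited fold was the ratio of the Aatoe2_IL to the wild-type mean, and the authors' log2 column was the log2 of that ratio. The authors' adjusted p-value was taken as printed in those tables.

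The table held 34220 genes, of which 9002 had no count in any library. The counters were left out of library sizes and tests. Reads counted outside genes came to between 13.4% and 21.5% of the reads counted in or outside genes or as ambiguous, depending on the library. Gene identifiers were paired with Arabidopsis names only in the authors' lists, which covered 627 distinct genes, 446 of them with an orthologue. Identifiers ending in a number above h1 (3682 genes) may be copies of the same gene that share reads, and their counts are uncertain. The identifier of TOE2 was not paired with a name in the sources used here, so its level was not analysed here.

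Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test after TMM normalization and edgeR's default filter on low counts, which left 19520 genes. All 12 libraries entered 1 fit with 4 groups and 8 residual degrees of freedom, and the common biological coefficient of variation was 0.130. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison. The 5 comparisons were Aatoe2_IL against wild type in the apex and in V3 buds, the difference between these 2 genotype effects (the interaction), and V3 buds against apex in each genotype. Fold changes are fitted log2 values with standard errors (SE). Each SE was derived as the absolute log2 fold change divided by the square root of the F statistic. It is approximate and unreliable where groups had few counts. Levels are CPM, computed from the deposited counts, as mean ± SD. These are read counts scaled to the total of reads in the genes that passed the filter, after TMM normalization. A group with 0 counts in all 3 libraries was given a floor of 3 counts over the group, and a group with 1 to 3 counts is reported as a ratio with an exact 95% interval. These intervals and floors cover counting error only.

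Design, alternatives, naming rule and 17 gene lists with 286 members were fixed before the data were examined. Of the list members, 39 had a name in the files. Because only genes chosen by the authors on these samples had names, no set test was run, and the counts per list are not independent evidence of a direction. Named genes were, per genotype comparison, list members past the threshold (all from lists about flowering, branching or hormones, up to 4 from others), the 8 largest rises and 8 largest falls with a name and no overlap between the groups, the 2 highest expressed members of the repressor, promoter, branching and other-tissue lists, and up to 2 rises and 2 falls without a name. For the interaction they were the 5 named genes with the smallest p in each direction, and for the tissue comparisons up to 3 members per list. Lists of heat shock, glucosinolate and morning clock genes were added after the names in the authors' tables had been seen.

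Replicate numbers were checked for pairing through the correlation of deviations from the group means. Between genotypes the same number did not mark a pair over all genes. Between apex and buds the correlations were 0.415, 0.320 and 0.239 in Aatoe2_IL, all above the limit of 0.1. In wild type they were 0.355, 0.0622 and 0.248, so that replicates 1 and 3 were above the limit and replicate 2 was not. No 2 libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of at least 3.22. The test was run on simulated counts with 200 changed genes among 19321. The changed genes were drawn only from those above a minimum mean count, so that recovery of genes with few reads was not measured. Libraries were simulated as independent, without the deviation shared by apex and bud samples of 1 number. For the apex it recovered 83.6% of genes changed 2-fold and 37.3% of those changed 1.5-fold, with 13 false among 159 calls. In V3 buds it recovered 83.6% at 2-fold and 35.8% at 1.5-fold, with 6 false among 152 calls. For the interaction, simulated with genes changed in either tissue, recovery was 66.4% at 2-fold and 11.2% at 1.5-fold.

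Alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, the replicate number as a block, fits of 1 tissue or genotype alone, a log2 fold change of at least 1, and leaving out each library. Leaving out both Aatoe2_IL replicate 1 libraries, the share of reads outside genes as a covariate, and a replicate block within genotype were added after seeing the data. The counts were set against other splits of the libraries, all 10 for 3 against 3, and 100 drawn of 200 possible labellings of the genotypes within tissues for the interaction. Overlaps were tested with Fisher's exact test (scipy 1.17.1).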

Results

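Transcript levels were measured in main shoot apices and in V3 buds of wild-type and Aatoe2_IL plants after 8 weeks of vernalization, with 3 libraries in each of the 4 groups. Reads assigned to genes ranged from 9411616 to 12309478 per library. They lay between 12032338 and 12309478 in wild-type apices, 9683738 and 11402861 in Aatoe2_IL apices, 9491985 and 10129450 in wild-type buds and 9411616 and 10580458 in Aatoe2_IL buds. At this depth 1 CPM is about 10 reads in a library, so that genes below 1 CPM rest on few reads. The first principal component of log CPM held 35.4% of the variance and separated the tissues, and the next held 19.7%, along which each Aatoe2_IL library lay below the wild-type libraries of its tissue. Gene names are those of the Arabidopsis orthologues that the authors' lists pair with the identifiers.

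Apices were compared to follow the role of AaTOE2 in flowering during vernalization, through the difference between Aatoe2_IL and wild type. In Aatoe2_IL apices CYP79B2 (Aa_G486300h1), which makes the precursor of indole glucosinolates, fell by 4.17 on the log2 scale (SE 0.65, edgeR adjusted p = 0.00772), from 27.4 ± 11.8 to 1.44 ± 1.99 CPM (SD, n = 3). It had 3.74, 0.306 and 0.286 CPM in Aatoe2_IL apex replicates 1, 2 and 3, and its log2 fold change was -6.48 without replicate 1. MYB28, a regulator of aliphatic glucosinolate synthesis, and CYP79B3, a close relative of CYP79B2, had 0 counts in Aatoe2_IL apices and were at least 19.4-fold and at least 15.1-fold lower than in wild type. The homeobox gene HB53 (Aa_G147020h1) rose by 2.49 (SE 0.46) from 0.984 ± 0.301 to 5.56 ± 3.99 CPM, and SHP2, a MADS-box gene of carpel development, rose by 2.49 (SE 0.53) from 0.250 ± 0.226 to 1.47 ± 0.399 CPM. The chaperone gene HSP101 (Aa_G639700h1) rose by 3.21 (SE 0.58), from 4.54 ± 2.34 to 42.6 ± 26.6 CPM.

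In total 215 of 19520 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in the apex, 57 higher and 158 lower in Aatoe2_IL, and 114 of them changed at least 2-fold. The other named rises were HSP23.6 (2.37), AT3G19790 (1.59), HSP17.6B (1.49), AT5G04840 (1.29) and AT3G53830 (1.25), all as log2 fold changes. Further falls were those of LSH9 (log2 fold change -3.23), the beta-glucosidase gene BGLU10 (-3.17), the sucrose transporter gene SWEET12 (-3.06), CYP71A27 (-3.04) and the zinc finger gene MGP (-2.94). Among genes without a name, Aa_G874400h1 had 1 count in wild-type apices, in replicate 1, and 314 in Aatoe2_IL, a ratio of 361 (95% interval 64.4 to 14310), and Aa_G647150h1 rose by 5.16 (SE 0.51). Aa_G107100h3 was at least 12.2-fold lower in Aatoe2_IL, with 0 counts there, and Aa_G680390h1 was lower by a ratio of 18.3 (4.75 to 156), with 2 counts against 42. The latter lost its call without each wild-type apex library and without Aatoe2_IL apex replicate 2 or 3. HSP101 has a further copy in the table (Aa_G639700h2, log2 fold change 1.54, edgeR adjusted p = 0.161), and reads may be split between the copies. Groups did not overlap for 214 of the 215 genes, against 20.8% of all genes tested and 10% by chance ranks.

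Of the 39 list members with a name, 3 passed in the apex, namely SHP2, HB53 and PIN3. PIN3, an auxin efflux carrier gene, fell by 1.56 on the log2 scale (SE 0.35, edgeR adjusted p = 0.0433), from 11.5 ± 2.07 to 3.82 ± 2.19 CPM. None of the 4 named SPL genes, transcription factor genes that promote flowering, passed edgeR's test, with a median log2 fold change of 0.69 and 2 members adjusted over the list alone. By the DESeq2 Wald test 2 of the 4 rose. AP1, a gene of floral meristem identity, had a log2 fold change of 1.56 (SE 0.46, edgeR adjusted p = 0.124), and TOE3, another APETALA2-like gene, one of 0.43 (edgeR adjusted p = 0.414). All 5 named members of the clock and photoperiod list were higher in Aatoe2_IL on average, with a median of 2.26, but none passed over all genes tested, while 5 did adjusted over the list alone. CCA1 stood at 3.12 (SE 0.82, edgeR adjusted p = 0.0846) and PRR9 at 2.26 (edgeR adjusted p = 0.0532). No member passed among the named genes for abscisic acid (6), cold (6), gibberellin (2) and cytokinin (2) lists, the flavonoid list (F3PH, 0.88) and the defence list (WRKY40, log2 fold change -2.55, edgeR adjusted p = 0.185). Adjusted over the list alone these lists gave 2, 1, 1, 1, 0 and 1 genes, and that count is not independent evidence, since the named genes were chosen by the authors on these samples. DRM2, the highest of the branching list, had 0.59 (edgeR adjusted p = 0.402), and the markers of other tissues, LHCB1.3 for green leaf and SEOR1 for phloem, had 0.49 and -0.56 without passing. No gene of the cell division list or the meristem and organ boundary list had a name.

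The apex count depended on single libraries. It was 35 without wild-type apex replicate 2, 41 and 47 without Aatoe2_IL apex replicates 2 and 3, 116 and 360 without wild-type apex replicates 3 and 1, 698 without Aatoe2_IL apex replicate 1 and 835 without both Aatoe2_IL replicate 1 libraries. Of the 21 named genes that passed, CYP79B2, Aa_G874400h1 and Aa_G647150h1 kept their call whichever library was left out. The call was lost by 16 without wild-type replicate 2, 16 without Aatoe2_IL replicate 2, 14 without Aatoe2_IL replicate 3, 8 and 5 without wild-type replicates 3 and 1, and 0 without Aatoe2_IL replicate 1. Of the 16 with more than 3 counts in each group, the fold of 6 moved by over 1.5 times without 1 library. The log2 fold change became -6.48 for CYP79B2, -4.82 for SWEET12, -2.16 for PIN3 and 1.73 for HB53 without Aatoe2_IL replicate 1, 3.45 for SHP2 without wild-type replicate 3 and 6.61 for Aa_G647150h1 without wild-type replicate 1.

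V3 buds were compared to follow the role of AaTOE2 in axillary branches. In Aatoe2_IL buds all 4 SPL genes with a name rose. The SPL list held 10 genes, and these 4 had names because the authors listed them as higher in these buds. SPL5 (Aa_G1050h1) rose by 2.71 on the log2 scale (SE 0.26, edgeR adjusted p = 6.34e-05), from 15.9 ± 3.54 to 104 ± 33.5 CPM, SPL3 (Aa_G438780h1) by 2.95 (SE 0.41) from 0.678 ± 0.407 to 5.34 ± 1.93 CPM, SPL4 (SE of the log2 fold change 0.32) from 2.81 ± 1.77 to 7.95 ± 1.87 CPM and SPL10 by 0.99 (SE 0.16). Among genes of floral organ identity, CRC (Aa_G690520h1), active in carpels and nectaries, rose by 1.85 (SE 0.21) from 6.06 ± 0.634 to 21.9 ± 3.97 CPM, and UFO (Aa_G355720h1), an F-box gene of floral patterning, fell by 1.83 (SE 0.19) from 31.8 ± 3.29 to 8.87 ± 1.98 CPM. GA20OX2 (Aa_G598100h1), a gibberellin synthesis gene, fell by 2.16 (SE 0.26) from 11.4 ± 1.01 to 2.55 ± 0.617 CPM, and GA2OX4, which acts in gibberellin breakdown, fell by 1.58 (SE 0.33).

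**Figure D1:**
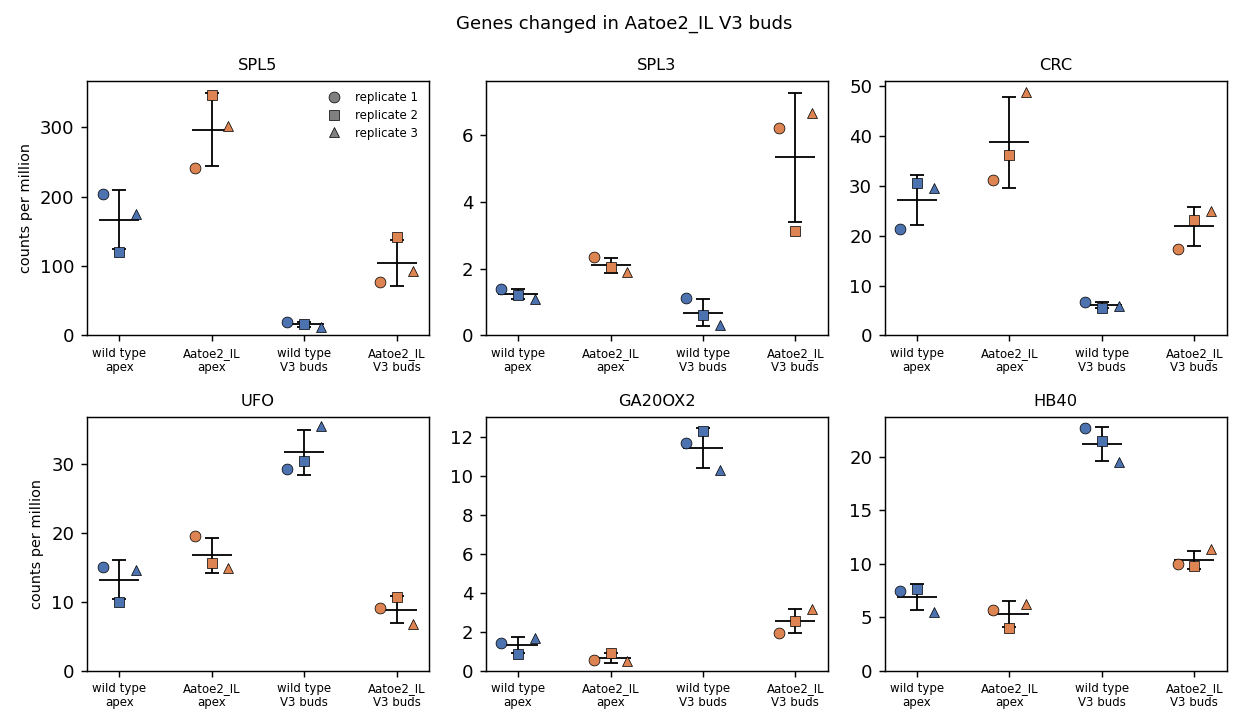
CPM in each library for 6 genes that changed in V3 buds, by genotype and tissue, with replicates 1, 2 and 3 as different symbols, bars at the mean and error bars of 1 SD (n = 3). SPL5, SPL3 and CRC were higher and UFO, GA20OX2 and HB40 lower in all 3 Aatoe2_IL bud libraries than in the 3 wild-type bud libraries.

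In V3 buds 967 of 19520 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 582 higher and 385 lower in Aatoe2_IL, and 394 changed at least 2-fold. Groups did not overlap for 963 of them, against 22.1% of all genes tested and 10% by chance ranks. AGL6, a MADS-box gene, had 3 counts in wild-type buds and 178 in Aatoe2_IL buds, a ratio of 58.8 (95% interval 19.8 to 288). The 3 counts were all in wild-type replicate 1, so that the size of this ratio rests on that library. Other large rises on the log2 scale were those of the zinc finger gene DOT5 (3.95), AT3G44970 (3.69), AT5G25970 (3.25), AT1G11850 (2.85) and the chaperone genes HSP90.1 (2.94) and HSP23.6 (2.92). The largest falls with a name were those of AT1G27030 (-3.77), CYP71A27 (-3.39), CYP79C2 (-3.33), AT4G13170 (-3.04), CYP79A2 (-2.81), which acts in benzylglucosinolate synthesis, IMD1 (-2.71), which acts in methionine-derived glucosinolate synthesis, AT2G30150 (-2.65) and PIL1 (-2.61), a shade-responsive transcription factor gene. Without a name, Aa_G874400h1 and Aa_G647150h1 had 0 counts in wild-type buds and were at least 107-fold and at least 70.7-fold higher in Aatoe2_IL buds. Aa_G370280h1 was lower by a ratio of 13.1 (1.97 to 558), with 1 count, in Aatoe2_IL replicate 3, against 13. It lost its call without each wild-type bud library and without Aatoe2_IL bud replicate 1 or 2. Aa_G193000h1 fell by 2.76 on the log2 scale and lost its call without each wild-type bud library and without Aatoe2_IL bud replicate 1 or 3.

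Of the 39 named list members, 18 passed in V3 buds. TOE3 rose by 1.57 (SE 0.32, edgeR adjusted p = 0.0114), whereas AP1 had at most 3 counts in each bud group and no fold is given. In the branching and dormancy list, the dark-inducible gene SEN1 rose by 1.73, the homeobox gene HB40 fell by 1.03, and 3 did not pass, among them DRM2 with 1.11 (edgeR adjusted p = 0.0748) and HB53 with 0.97 (edgeR adjusted p = 0.0724). All 5 passed adjusted over the list alone. Of 6 named genes of the abscisic acid list, RD29A rose by 1.12, RD22, a dehydration-responsive gene, fell by 1.58, and 4 did not pass. Of 6 named cold response genes 3 rose, namely KIN2 (1.11), COR413-PM1 (1.15) and RD29A. Adjusted over the list alone, 4 genes passed in each of these lists. CKX1, a cytokinin oxidase gene, fell by 1.02 (SE 0.28, edgeR adjusted p = 0.0498), and LOG7 did not pass. Neither auxin gene passed, with GH3.2 at 1.06 (edgeR adjusted p = 0.0824) and PIN3 at 0.21, nor did the 5 clock genes (median 1.25, 5 adjusted over the list alone), F3PH (1.43) or WRKY40 (2.33). Both markers of other tissues rose, LHCB1.3 of green leaf by 1.12 (SE 0.18, 1741 ± 70.5 to 3772 ± 812 CPM) and SEOR1 of phloem by 1.47 (SE 0.26). These list counts are not independent evidence of direction, because the genes have names through the authors' own lists.

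The bud count was 437 without wild-type bud replicate 2, 526 and 410 without Aatoe2_IL bud replicates 2 and 3, 621 in a fit of bud libraries alone and 2134 with the share of reads outside genes as a covariate. Of 37 named genes that passed, 23 kept their call without each library in turn, 4, 11 and 7 lost it without wild-type bud replicates 1, 2 and 3 and 2, 7 and 8 without Aatoe2_IL bud replicates 1, 2 and 3. Those that lost it in at least 1 case included TOE3 (without wild-type replicate 2), SPL4 (without wild-type replicate 2 or 3 or Aatoe2_IL replicate 2), GA2OX4 (without wild-type replicate 2 or Aatoe2_IL replicate 3), RD29A, COR413-PM1, HSP90.1 and CKX1. Of the 33 with more than 3 counts in each group, the fold of 5 moved by over 1.5 times. The log2 fold change became 2.15 for SPL4, 5.04 for AT3G44970, 3.96 for AT5G25970 and 3.84 for HSP90.1 without wild-type bud replicate 1 and -4.47 for Aa_G193000h1 without Aatoe2_IL bud replicate 2.

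Genes called in both tissues were compared to see how far the genotype effects coincided. Shared calls were 34 genes that rose and 45 that fell in both, and 0 moved in opposite directions. Independent lists of these sizes would share 1.70 and 3.12 genes (Fisher's exact test, one-sided, p = 1.46e-37 and p = 1.34e-39). However, apex and bud libraries of 1 replicate number deviated together in Aatoe2_IL and, for replicates 1 and 3, in wild type, and these p-values do not account for that. HSP23.6, HSP17.6B, HSP101 (Aa_G639700h1), the clock gene EPR1, AT3G19790, AT5G04840, AT3G53830 and the unnamed Aa_G874400h1 and Aa_G647150h1 were among those that rose in both tissues. CYP71A27, PIL1 and the unnamed Aa_G680390h1 and Aa_G370280h1 were among those that fell in both. The total of 79 was 20 without Aatoe2_IL apex replicate 2, 22 without wild-type apex replicate 2, 28 without Aatoe2_IL apex replicate 3, 46 without wild-type apex replicate 3, 47 without wild-type bud replicate 2, 45 and 51 without Aatoe2_IL bud replicates 2 and 3, 126 without Aatoe2_IL apex replicate 1 and 300 without both Aatoe2_IL replicate 1 libraries.

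**Figure D2:**
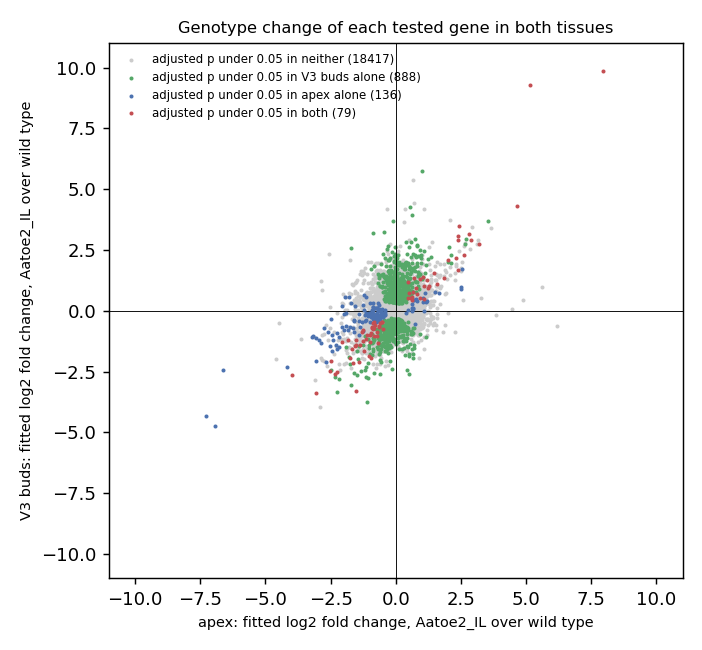
Fitted log2 fold change of Aatoe2_IL over wild type for each of 19520 genes, in the apex on the horizontal axis and in V3 buds on the vertical axis, coloured by the comparison in which the gene passed. The 79 genes that passed in both lie in the quadrants of equal sign, 888 passed in V3 buds alone and 136 in the apex alone, and fitted values of genes without counts in a group depend on the prior count.

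Whether the genotype effect differed between V3 buds and apex was tested by the interaction. UFO, which fell in Aatoe2_IL buds, had a log2 fold change of 0.34 in apices (edgeR adjusted p = 0.378), and its interaction was -2.18 (SE 0.26, edgeR adjusted p = 0.00254). KNATM (Aa_G777300h1), a gene related to the KNOX class of meristem regulators, had an interaction of -2.38 (SE 0.36) and went from 22.8 ± 3.25 to 6.25 ± 1.65 CPM in buds and from 1.57 ± 0.118 to 2.24 ± 0.625 CPM in apices. The arginine decarboxylase gene ADC1 had an interaction of 1.80 (SE 0.19, edgeR adjusted p = 0.00193), with 17.1 ± 1.74 CPM in wild-type and 58.9 ± 7.71 CPM in Aatoe2_IL buds, against 35.3 ± 0.439 and 35.0 ± 6.20 CPM in apices. The anion transporter gene CLC-A (1.72), the receptor kinase gene XIP1 (2.22), the sucrose synthase gene SUS6 (2.37) and the ion channel gene CNGC4 (1.96) likewise had a higher effect in buds, and FMOGS-OX6 (-1.81), a glucosinolate oxygenase gene, AT3G15240 (-2.62) and AT1G23000 (-1.27) a lower one. Of the 39 list members 4 passed, namely SPL5 (1.88), CRC (1.34) and SEOR1 (2.04) with a higher and UFO with a lower effect in buds. Altogether 202 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 149 with a higher and 53 with a lower effect in buds. This fit leaves out the replicate number, which paired apex and bud samples in Aatoe2_IL and, for replicates 1 and 3, in wild type. With the number as a block within genotype, added after seeing the data, 1986 genes passed. The count was 43 without both Aatoe2_IL replicate 1 libraries, where FMOGS-OX6 and AT1G23000 lost their call, 91 and 40 without Aatoe2_IL apex replicates 2 and 3, 61 and 45 without Aatoe2_IL bud replicates 1 and 3, 391, 42 and 40 without wild-type apex replicates 1, 2 and 3, and 45 and 118 without wild-type bud replicates 2 and 3, and all 10 genes with the smallest p kept their call without each of these single libraries.

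Tissues were compared within each genotype. In wild type SPL4, SPL5 and SPL10 were lower in V3 buds than in apices, with log2 fold changes of -3.78, -3.39 and -1.41, as were TOE3 (-2.43), CRC (-2.16) and SEOR1 (-2.61). AP1 had 2 counts in wild-type buds and 37 in apices, which was 14.8-fold more in apices (95% interval 3.83 to 127). Its size rests on wild-type bud replicate 1, which held both bud counts. CKX1 (4.21), HB53 (4.28), HB40 (1.62), GA2OX4 (1.59), RD22 (1.52) and UFO (1.26) were higher in buds, as was GA20OX2 with 11.4 ± 1.01 CPM in buds and 1.32 ± 0.420 CPM in apices. In total 2184 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 949 higher and 1235 lower in buds, among them 14 of the 39 list members. The count was 1386 and 1258 without wild-type apex replicates 2 and 3, and among the 14 named genes only AP1 lost its call, without wild-type bud replicate 2, while SPL4 became -4.43 without wild-type bud replicate 1.

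In Aatoe2_IL the same 3 SPL genes were lower in buds, with log2 fold changes of -2.51 for SPL4, -1.51 for SPL5 and -1.03 for SPL10, as were TOE3 (-1.28), CRC (-0.82), LOG7 (-1.50), a cytokinin activation gene, and UFO (-0.91), which in wild type was higher in buds. SPL3, the remaining named member of that list, was higher in buds (1.33, edgeR adjusted p = 0.0336). AP1 had 1 count in Aatoe2_IL buds, in replicate 2, and 95 in apices, a ratio of 88.5 in favour of apices (95% interval 15.5 to 3532). HB53 (2.75), HB40 (0.96), NCED3 (2.27), an abscisic acid synthesis gene, and CKX1 (4.37) were higher in buds, as was GA20OX2 with 2.55 ± 0.617 CPM in buds and 0.638 ± 0.243 CPM in apices. Here 1107 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 619 higher and 488 lower in buds, among them 14 of the 39 list members, and 2378 passed with the replicate number as a block within genotype, under which the 13 named genes passed too. The count was 629 and 651 without Aatoe2_IL apex replicates 2 and 3 and 650 without Aatoe2_IL bud replicate 3. UFO lost its call without Aatoe2_IL bud replicate 3, TOE3 without that library or Aatoe2_IL apex replicate 2, and CRC without Aatoe2_IL apex replicate 3 or bud replicate 1. Without Aatoe2_IL apex replicate 1 HB53 became 3.52, NCED3 3.08 and CKX1 5.44.

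Several genes varied between the replicates of Aatoe2_IL in both tissues, and the following were chosen after their values were seen. HSFA2 (Aa_G290430h1), a heat shock transcription factor gene, had 24.4, 256 and 293 CPM in Aatoe2_IL apex replicates 1, 2 and 3 and 40.9, 12.7 and 25.5 CPM in wild type. In buds it had 31.6, 209 and 285 CPM in Aatoe2_IL and 44.8, 26.0 and 18.6 CPM in wild type. CCA1 (Aa_G177850h1) had 5.82, 81.9 and 33.3 CPM in Aatoe2_IL apices and 8.19, 1.99 and 3.38 CPM in wild type. GSTF9 (Aa_G85970h1), a glutathione transferase gene linked to glucosinolate synthesis, had 266, 100.1 and 100.9 CPM in Aatoe2_IL apices and 531, 420 and 324 CPM in wild type. None of these 3 genes passed edgeR's test in either tissue, with adjusted p of 0.0988, 0.0846 and 0.0691 in the apex.

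**Figure D3:**
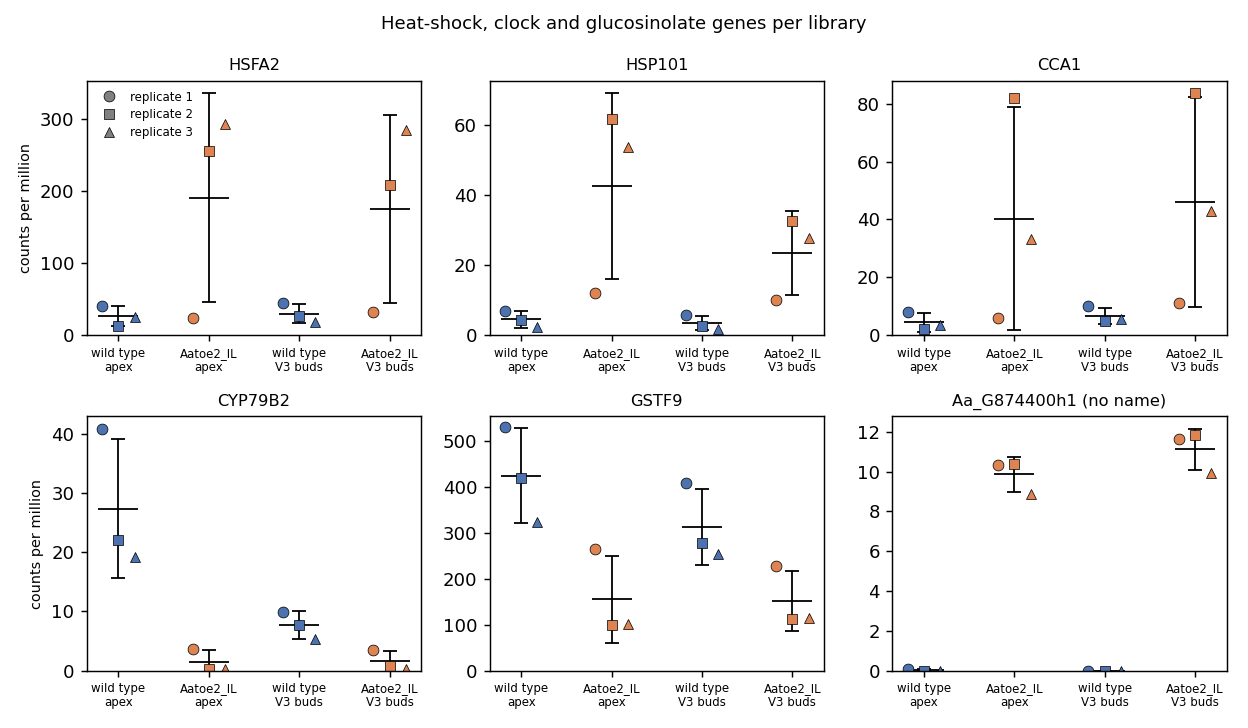
CPM in each library for 6 genes, by genotype and tissue, with replicates 1, 2 and 3 as different symbols, bars at the mean and error bars of 1 SD (n = 3). HSFA2 and CCA1 were near wild type in Aatoe2_IL replicate 1 and higher in replicates 2 and 3, whereas Aa_G874400h1 lay between 8.86 and 11.8 CPM in all 6 Aatoe2_IL libraries and at or near 0 in wild type.

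The authors' deposited tables listed 125 genes higher and 185 lower in Aatoe2_IL apices, and 270 higher and 152 lower in V3 buds. Of these 732 entries 436 passed edgeR's test in the same direction, 109 of 310 in the apex and 327 of 422 in buds, and 0 passed in the opposite direction. All 716 entries that could be tested had the same sign. With the DESeq2 Wald test 533 entries passed in the same direction. In the authors' deposited table SPL5 had a fold of 6.59 in V3 buds with an adjusted p of 6.39e-46, and UFO had a log2 fold change of -1.84. HSFA2 had a fold of 7.31 in the apex in the authors' deposited table, with an adjusted p of 9.24e-69. The lists come from the same libraries and are not independent evidence.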

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

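All tests of the replicate pattern, the shared wild-type libraries, the buds against both other groups, the replicate block within genotype and the gap between tissue counts were chosen after the result was seen, whereas the test of a single share of apex RNA and the other labellings of the samples were planned first.

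The genotype effect differed between V3 buds and apex for 202 genes by the interaction test. Among named genes the effect was higher in buds for SPL5 (1.88), CRC (1.34), SEOR1 (2.04), ADC1 (1.80), CLC-A (1.72), XIP1 (2.22), SUS6 (2.37), CNGC4 (1.96), DOT5 (3.34), AT5G25970 (3.70) and AT1G11850 (2.47), and lower for UFO (-2.18), KNATM (-2.38), FMOGS-OX6 (-1.81), AT3G15240 (-2.62) and AT1G23000 (-1.27), all on the log2 scale. Of 100 labellings of the genotypes within tissues, drawn from 200 possible, 4 gave at least 202 genes, the real one included, a share under 0.05 of those drawn, and the undrawn ones were not run. The highest other drawn gave 423, and the 3 others kept every bud in its own genotype and exchanged 2 of the 3 apices of each genotype, among them Aatoe2_IL apex replicates 2 and 3, so that a genotype effect shared by both tissues counts as a difference between them, and why these 3 gave more genes was not tested. Every drawn labelling with more than 5 genes kept each bud in its own genotype. Labellings that mix the genotypes of the buds put genotype differences into the spread within groups, which can lower the count. The share therefore does not by itself test whether the genotype effect differs between the tissues. The labellings were drawn for apices and buds apart and fitted without a replicate block. Apex and bud libraries of 1 number nevertheless deviated together in Aatoe2_IL and, for replicates 1 and 3, in wild type, and with a block within genotype 1986 genes passed.

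Heat shock and morning clock genes were high in Aatoe2_IL replicates 2 and 3 and near wild type in replicate 1, in apices and buds alike. Of 28 such genes, replicates 2 and 3 lay above all wild-type libraries for 28 in the apex and 27 in buds, and replicate 1 did so for 12 and 10. These 28 genes had names because the authors listed them as higher in Aatoe2_IL on the same libraries. A position above wild type thus follows in part from that choice. Wild type varied by replicate too, in the other direction. There replicate 1 was the highest library for 13 of 19 heat shock genes in the apex and 14 in buds. The same held for 6 and 7 of 9 morning clock genes, while in Aatoe2_IL it held for 0 genes of either group. A wrong label on both replicate 1 libraries is argued against, since among genes called at 4-fold or more without them replicate 1 lay past the midpoint towards Aatoe2_IL for 33.33% in the apex (95% interval 25.1 to 42.4) and 66.4% in buds. Library quality stays open, since the share of reads outside genes was larger in both replicates 2 and 3 than in replicate 1 in 1 of the 2 tissues, the apex, while in buds it was 17.1% in replicate 1, 19.0% in replicate 2 and 15.4% in replicate 3. A growth or harvest batch shared by the apex and buds of 1 number in Aatoe2_IL may account for the pattern, as every same-numbered pair of Aatoe2_IL deviated together over the other genes, with a lowest correlation of 0.228. In wild type the correlations of replicates 1, 2 and 3 over these genes were 0.352, 0.0612 and 0.247. Deviations from a mean of 3 libraries depend on each other. A shift of replicate 1 shared by apex and buds can therefore raise all 3 correlations, so that they are not separate evidence of a batch for each number. An effect of the genotype that varies between plants stays open and was not tested.

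Aatoe2_IL buds lay nearer to the apex than wild-type buds. Of 1235 genes higher in the wild-type apex, 240 rose and 18 fell in Aatoe2_IL buds, and of 949 higher in wild-type buds 8 rose and 146 fell. In Aatoe2_IL apices 9 of the 1235 rose and 64 fell (median log2 fold change -0.193), and 11 of the 949 rose and 9 fell (median 0.156). Those apex changes share the wild-type apex libraries with the tissue difference. The bud change and the wild-type tissue difference both use the wild-type bud libraries. Their covariance was 2.69 times that expected from the spread of those libraries, but 1.34 times without wild-type bud replicate 2, so that this source cannot be told apart from a real shift with 3 libraries. Apex tissue mixed into the Aatoe2_IL buds may account for part of the shift. The share of apex RNA was computed for 222 genes higher in the apex and 115 higher in buds, with median bud log2 fold changes of 1.32 and -0.55. Over all 1235 and 949 genes these medians were 0.31 and -0.24. The 222 genes needed a median share of 29.6% (quartiles 11.9 and 48.8) and the 115 genes 42.8% (quartiles -3.14 and 64.5), a ratio of 1.45. With the lower quartile of the latter below 0, a single share was met only loosely. Mixing puts Aatoe2_IL buds between wild-type buds and Aatoe2_IL apices. It is argued against for a part of the 967 genes called in buds, as 175 were called in the same direction against both (108 without Aatoe2_IL bud replicate 2 and 58 without replicate 3). The threshold allows 55.4 false calls among the 1107 genes between Aatoe2_IL tissues (42.4 and 32.5 without these libraries). Both calls use the same 3 Aatoe2_IL bud libraries, and the allowed number does not cover a deviation that these share. A change of bud development in Aatoe2_IL stays open and untested.

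Fewer genes differed between buds and apex in Aatoe2_IL (1107) than in wild type (2184), a gap of 1077 genes. Of the same 100 labellings out of 200 possible 1, the real one, gave a gap as large, and the highest other drawn gave 985, a share under 0.05 of those drawn, with all libraries. The labelling with 985 exchanged wild-type bud replicate 3 and Aatoe2_IL bud replicate 2 alone. Labellings that mix the genotypes put genotype differences into the spread within groups. This can lower the tissue counts, so that the share does not by itself test equal tissue differences in the genotypes. The gap was 283 without wild-type apex replicate 3, 295 without replicate 2, 452 without wild-type bud replicate 1, 486 without replicate 2, 596 with each genotype fitted alone and 2446 with the replicate block within genotype (4824 against 2378), so that its size rests on single wild-type libraries and on the model, and other labellings were not counted for these. The sources weighed for the shift of the buds bear on this gap too.

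The remaining counts had too few splits of the samples to give a share under 0.05, as 3 libraries against 3 make 10 splits. The real split was the 1 with as many genes in each comparison, with 215 genes in the apex, 967 in V3 buds, 2184 between tissues in wild type and 1107 in Aatoe2_IL, and the highest of the other splits gave 0.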

How the results depend on the processing

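DESeq2 size factors left every count within 1.5 times. Without a filter on low counts the apex gave 400 genes, the overlap of tissues 132 and the list members 35 (21 as reported, apex and buds together). The DESeq2 Wald test gave 557 in the apex, 565 for the interaction and 135 shared, and DESeq2 on 1 tissue alone 547 in the apex, 135 shared and 32 list members. On the simulated counts the DESeq2 Wald test over all libraries made 34 false among 184 calls in the apex and 22 among 178 in buds. With edgeR these were 13 among 159 and 6 among 152. The edgeR fit of 1 tissue alone gave 129 in the apex, 621 in buds and 42 shared. A log2 fold change of at least 1 left 114, 394, 133, 885 and 563 genes in the apex, buds, interaction and the tissue comparisons of wild type and Aatoe2_IL, and 41 shared, by construction.

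The planned replicate block over all libraries gave 314 genes in the apex, 1365 in buds, 253 for the interaction, 2532 and 1264 for the tissue comparisons and 129 shared. The block in 1 tissue alone gave 45 in the apex, 589 in buds and 24 shared. Between genotypes same-numbered samples correlated at -0.0308, -0.285 and 0.0896 in the apex and -0.00717, -0.0707 and 0.0998 in buds. The numbers thus did not mark pairs over all genes there, which leaves open a pairing in some genes. The block within genotype, added after seeing the data, gave 1986 for the interaction, 4824 for wild-type tissues and 2378 for Aatoe2_IL tissues, where the numbers pair the samples and the block ended no call of the 13 named genes.

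Also added after seeing the data, leaving out both Aatoe2_IL replicate 1 libraries gave 835 in the apex, 43 for the interaction, 300 shared and 41 list members, and the share of reads outside genes as a covariate gave 2134 in buds and 409 for the interaction. Leaving out in turn each library of the groups compared gave 35 to 698 genes in the apex, 410 to 1017 in buds, 40 to 391 for the interaction, 1258 to 2455 and 629 to 1066 for the tissues of wild type and Aatoe2_IL, 20 to 126 shared, 327 to 544 for the overlap with the authors' deposited lists and 15 to 30 list members. Since all groups share 1 fit, leaving out a wild-type library moved the count of Aatoe2_IL tissues too, up to 1369 without wild-type bud replicate 1. Except for the fold limit, the cause of these moves was not tested.

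The values of named genes under the alternatives kept direction and side of the threshold in 1486 cases, passed no longer in 149 and passed newly in 10. AP1 in buds, leaving out each library in turn, ranged from -2.75 (without Aatoe2_IL replicate 2) to 1.97, a reversal, without wild-type replicate 1, on at most 3 counts per group. A call under every alternative run was kept by 3 of 21 named genes in the apex, 22 of 37 in buds, 8 of 10 for the interaction, 13 of 14 in wild-type and 9 of 13 in Aatoe2_IL tissues. Depth limits genes under 1 CPM. Alternatives for the TOE2 level and for set tests were not run, because no identifier was paired with TOE2 and only listed genes had names.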

Other observations

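The groups of heat shock, morning clock and glucosinolate genes were assembled after the authors' lists had been seen, and leaving out both Aatoe2_IL replicate 1 libraries was chosen because heat shock genes were near wild type in them, so that the calls gained without them follow from that choice and the counts here are a description, not tests. Of 19 heat shock factor and chaperone genes with a name, 3 rose in the apex (HSP101, HSP23.6 and HSP17.6B) and 5 in V3 buds by edgeR's quasi-likelihood test, while without both Aatoe2_IL replicate 1 libraries 19 rose in the apex and 17 in buds. In the authors' apex lists 19 entries of this group were higher and 0 lower, against 61 and 137 for other named genes, and in V3 buds 11 and 0, against 197 and 94. Of 9 morning clock genes, EPR1 (1.08 in the apex, 1.02 in buds) rose in each tissue, and 9 and 7 rose without the replicate 1 libraries. Their entries in the authors' lists were 9 higher and 0 lower in the apex (71 and 137 for other named genes) and 8 and 0 in buds (200 and 94).

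Glucosinolate synthesis genes were on the lower side. Of 12 named and tested, 6 fell in the apex and 1 in V3 buds, and 9 and 7 fell without the Aatoe2_IL replicate 1 libraries. The group leaves out further genes of this route or linked to it that also fell in V3 buds, among them CYP79A2 (-2.81), CYP79C2 (-3.33), FMOGS-OX6 (-1.52) and IQD1 (-2.55), so that the count of 1 understates the falls there. In the authors' lists 13 entries were lower and 0 higher in the apex (124 and 80 for other named genes) and 4 and 0 in buds (90 and 208). CYP83B1 had 324, 215 and 221 CPM in wild-type apex replicates 1, 2 and 3 and 174, 66.4 and 72.6 CPM in Aatoe2_IL. SOT16, a sulfotransferase gene of the same route, had 12.3, 5.62 and 4.31 CPM in wild type and 2.17, 0.408 and 0.762 CPM in Aatoe2_IL, and replicate 1 was the highest of its group in both genotypes for 9 of the 12 genes in the apex and 8 in buds. These groups were assembled from genes that the authors had selected on the same libraries, so the counts do not show enrichment.

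Replicates 2 and 3 differed less from each other than from replicate 1 in each of the 4 groups. The chi-square per degree of freedom between replicates 2 and 3 was 3.90 in wild-type apices, 4.36 in Aatoe2_IL apices, 3.22 in wild-type buds and 6.19 in Aatoe2_IL buds, against 7.17 to 16.8 for the pairs with replicate 1.

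RAB18, a dehydrin gene, had 277 CPM in wild-type apex replicate 2 against 30.4 and 13.0 CPM in the others, and RD29B had 24.5 against 2.11 and 0.423 CPM. VIN3, a gene induced by cold, had 7.10, 18.9 and 35.4 CPM in Aatoe2_IL bud replicates 1, 2 and 3 and 5.65, 7.49 and 7.71 CPM in wild-type buds, without passing (log2 fold change 1.56, edgeR adjusted p = 0.0618).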
